A study of Homo sapiens with 12 samples.

How the data were processed

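The samples were 12 libraries of the A549 cell line in 3 groups of 4: control, 10 ng/mL TGF-β1, and TGF-β1 with 40 mM sodium acetate, collected after 2 days. Per the labels, total RNA was made into stranded libraries after removal of ribosomal RNA and sequenced as paired reads of 75 bp from 2 ends. The tools named by the submitters are bcl2fastq for base calls, HISAT2 for alignment to hg38, and limma; their versions, the counting tool, its strand setting and the annotation release are not given in the sources used here. If the counter ignored the strand, genes that overlap on opposite strands share reads, and reads that map to several copies of a gene may be lost or assigned to any of them. For that reason antisense genes and genes with near-identical copies (histone genes, the CGB genes, members of the AKR1 families, the PCDHA cluster) are treated as uncertain.

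The deposited files are 2 tables of genes, each with 8 columns of raw counts in units of counts, and the authors' own comparison as a log2 fold change with its p-value and q-value. With the columns placed as below, the log2 fold changes in the authors' deposited tables had the sign of the later-named group minus the earlier for 91.8% and 88.4% of genes, so positive values were read that way. The authors' q-values reach at most 0.234 and 0.242 where their p-values reach 1.00, so they are not Benjamini-Hochberg values. At a q below 0.05 the authors' deposited tables hold 18099 of 24459 genes (9366 higher) for TGF-β1 against control and 17823 of 24745 genes (9503 higher) for acetate. The tables keep genes with more than 0.1 CPM in at least 4 libraries, as checked on the values. A further 32 columns of values per library, on another scale, were not used.

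The count columns carry short codes that match no sample label. One set of 4 columns stands in both tables, with identical counts in all 23771 genes the tables share. Each set was placed in its group from this arrangement and from the names the authors gave the tables: the shared set as TGF-β1, the set found only in the table named for control and TGF-β1 as control, and the set found only in the table named for TGF-β1 with acetate as acetate. Neither the order of the columns nor the level of any gene was used. This placement is not stated in any sample label, so a wrong table name would change every comparison. Which replicate a column represents is not shown, so libraries carry their column codes here (S1 to S4 control, S15 to S18 TGF-β1, S22 to S25 acetate) and no pairing was used.

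Gene identifiers with versions were matched to GENCODE release 29 by their unversioned part for 99.1% of genes in each table; 89.5% and 89.6% had the same version, all with the same coordinates on hg38. Gene types come from that annotation, and transcript lengths and GC content from the longest transcript of each gene in it. Mitochondrially encoded genes were not analysed here. Pairs of libraries within each group were compared by a chi-square statistic per degree of freedom, which ran from 3.95 to 17.1, so no library was a duplicate of another.

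Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), scaled by TMM factors and tested with glmQLFit and glmQLFTest, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. TGF-β1 was compared with control and acetate with TGF-β1 within the table that holds both groups, and acetate with control in a fit of all 12 libraries joined on shared genes. Levels are CPM with TMM-adjusted totals from that joint fit. Gene lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the 31 lists with at least 5 tested members. Lists, comparisons, tests and most alternatives were fixed before the data were examined. Of 930 distinct genes in the lists, 847 matched a gene in the tables. A gene list and some genes that the plan names are not reported here, although counts over all genes and over all lists include them. The 35 lists cover TGF-β and mesenchymal programmes, epithelial identity, metabolism, stress responses, cell cycle, immunity and markers of other cell types.

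Genes are named by a rule set beforehand. It takes, in each of the first 2 comparisons, the 6 largest rises and the 6 largest falls among genes with a symbol, leaving out pseudogenes, unnamed loci and small RNAs, at or above the median level whose groups do not overlap and whose adjusted p is below 0.05. It adds the 3 genes with the smallest p in each list (4 where camera passes), 14 genes chosen in advance, and the 5 genes with the largest product of both changes in each direction. Where the text names fewer list members than the rule gives, the rest are left undescribed; some genes are also given in a comparison other than the one that named them, and the genes of families in the closing part were picked after seeing the data.

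The relation between both effects was measured as the correlation across genes with the 4 TGF-β1 libraries divided, 2 to each comparison, over 6 ordered splits, with log CPM at a prior count of 2, beside 20 simulations without effects. Alternatives were median-of-ratios size factors, no filter and a stricter filter (mean CPM of at least 1), DESeq2 1.42.0, limma-voom, a joint fit of all libraries, a 2-fold limit, each library left out in turn, camera with an estimated correlation and fry. Scaling by library totals only and thinning to the smallest library total were added after seeing the data.

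The procedure was tested on simulated data. Of 50 simulated 2-fold changes edgeR recovered 40 for TGF-β1 and 45 for acetate with the right sign, and all simulated 4-fold changes (50 of 50 and 48 of 48). It called 25 of 21521 and 13 of 21776 unchanged genes. Camera passed the shifted list each time, and 1 of 30 and 0 of 30 unshifted lists. Genes were simulated independently, so this does not test camera at its preset correlation where members of a list vary together.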

Results

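The data are gene counts from A549, a human lung adenocarcinoma cell line with alveolar epithelial features. The cells were left untreated (control), given 10 ng/mL TGF-β1, or given TGF-β1 together with 40 mM sodium acetate, for 2 days. TGF-β1 is a growth factor that drives epithelial cells towards a mesenchymal state, and acetate is a short-chain fatty acid that cells turn into acetyl-CoA. Each of the 3 groups had 4 libraries of stranded, ribosomal-RNA-depleted total RNA. The count columns carry no sample labels, so each column was placed in its group by the table or tables that hold it, read with the authors' names for those tables. No label states that placement, and every comparison rests on it.

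Total counts per library ran from 38400896 to 53055990 in the control group, from 37202599 to 53936023 in the TGF-β1 group and from 34698057 to 41575904 in the acetate group. At these depths 3 counts equal between 0.0556 and 0.0865 CPM, a floor that covers counting error only. Levels below are CPM from normalised counts, given as mean ± SD (n = 4), with positions on genome build hg38. The labels do not say whether the 4 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

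TGFBI, a secreted matrix protein named for its induction by TGF-β, took the largest share of the counts in the TGF-β1 libraries and in the acetate libraries. Genes of small RNAs such as the signal recognition particle RNA took 7.14 ± 0.822% of the counts in control, 6.54 ± 0.482% with TGF-β1 and 5.24 ± 0.425% with acetate (n = 4). The 10 most abundant genes took 9.47 ± 0.909%, 10.3 ± 0.544% and 7.86 ± 0.411% of the counts in the same order. Shares for cytosolic ribosomal protein genes were 4.11 ± 0.0274%, 4.67 ± 0.0738% and 3.44 ± 0.120%.

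The first question was which genes TGF-β1 alone changed. COL22A1, a collagen of tissue junctions (ENSG00000169436.16, chromosome 8, 138588235 to 138914006), rose from 0.166 ± 0.104 CPM in control to 73.4 ± 3.42 with TGF-β1. IGFBP5, a secreted binder of insulin-like growth factors (ENSG00000115461.4, chromosome 2, 216672105 to 216695525), rose from 1.18 ± 0.131 to 188 ± 1.63 CPM, and the pentraxin gene NPTX1 (ENSG00000171246.5, chromosome 17, 80467148 to 80477843) rose from 9.57 ± 0.749 to 1394 ± 59.1 CPM. In the other direction, AGR2, a protein disulfide isomerase of secretory epithelia (ENSG00000106541.11, chromosome 7, 16791811 to 16833433), fell from 300.5 ± 10.9 to 1.59 ± 0.176 CPM. CDH1, which encodes the epithelial adhesion protein E-cadherin (ENSG00000039068.18, chromosome 16, 68737225 to 68835548), fell from 58.7 ± 2.80 to 1.46 ± 0.394 CPM.

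The growth factor genes AREG and EREG, both ligands of the EGF receptor, fell from 65.8 ± 4.47 to 0.425 ± 0.153 CPM and from 275 ± 6.43 to 4.34 ± 0.298 CPM. FGA, which encodes the fibrinogen alpha chain, fell from 71.1 ± 1.76 to 0.586 ± 0.0906 CPM. Among the 6 largest increases of genes at or above the median level were also WNT5B, VSTM4 and CGB8, with log2 fold changes of 7.02, 6.90 and 6.71. The 6 largest decreases at or above that level also held the mucin gene MUC5B (-6.46 on the log2 scale) and CYP4F3 (-6.05). CGB8 belongs to a cluster of near-identical chorionic gonadotropin genes that can share reads, so its own level is uncertain. Of these 12 genes and CDH1, the largest edgeR adjusted p was 1.8e-14, for MUC5B.

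In all, 14742 of 22051 tested genes passed in the edgeR quasi-likelihood test, 7518 higher and 7224 lower, at an adjusted p below 0.05. At least 2-fold changes were found for 1968 genes upward and 1915 downward. The 4 libraries of each group did not overlap for 61.4% of tested genes, against 2.86% given by chance. DESeq2 called 14240 genes and limma-voom 14741.

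SMAD target and feedback genes, which respond directly to TGF-β receptors, mostly rose: 19 of 25 tested rose and 4 fell, with a median log2 fold change of 1.14 (camera adjusted p = 1.8e-18). TGFBI rose from 1328 ± 41.5 to 14959 ± 425 CPM. Log2 fold changes were 3.45 for CTGF, 2.57 for TGFBR1 and 1.33 for SMAD7, the last an inhibitor of the same receptors.

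Mesenchymal genes and transcription factors of the epithelial to mesenchymal transition rose in 25 of 32 cases and fell in 4 (median 1.45, camera adjusted p = 2.3e-24). The matrix proteoglycan gene SPOCK1, the ectonucleotidase gene NT5E and the cadherin gene CDH11 rose by log2 fold changes of 3.99, 2.59 and 6.04. N-cadherin (CDH2), vimentin (VIM) and fibronectin (FN1) rose by 1.45, 1.36 and 2.09. Of the transcription factors, SNAI2 rose by 2.30 and ZEB1 by 0.49, the latter with an edgeR adjusted p of 1.2e-08.

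Epithelial junction and identity genes went the other way, with 27 of 40 lower and 7 higher (median -1.09, camera adjusted p = 3.2e-08). Log2 fold changes were -5.32 for CDH1, -3.59 for CLDN1, -2.38 for ELF3 and -1.60 for CLDN2; CLDN1 and CLDN2 encode tight junction claudins.

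Collagen genes rose in 18 of 25 cases and fell in 4 (median 1.56, camera adjusted p = 7.3e-15). COL1A1, the main chain of fibrillar type I collagen, rose from 9.08 ± 0.854 to 295 ± 8.23 CPM, and log2 fold changes were 3.77 for COL4A1, 3.12 for COL5A1 and 3.08 for COL4A2. Matrix proteases and their inhibitors rose in 19 of 24 cases and fell in 2 (median 1.69, camera adjusted p = 4.8e-16), with log2 fold changes of 4.77 for MMP2, 4.33 for ADAM19, 3.83 for TIMP2 and 3.66 for SERPINE2. Of 20 integrin genes 10 rose and 6 fell (median 0.22, camera adjusted p = 2.9e-05), among them ITGA11 (4.86 on the log2 scale), ITGA1 (3.53), ITGB6 (2.65) and ITGAV (1.36). With single libraries left out the integrin median ran from 0.18 (without control library S1) to 0.37 (without TGF-β1 library S15). Actin cytoskeleton genes rose in 27 of 31 cases and fell in 3 (median 0.86, camera adjusted p = 3.5e-10, and adjusted p = 0.077 with an estimated correlation). TAGLN, TPM1 and TAGLN2 rose by 4.67, 2.45 and 1.51 on the log2 scale, and PDLIM5 fell (-2.21).

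NRF2 target genes, which encode antioxidant and detoxifying enzymes, fell in 30 of 32 cases and rose in 2 (median -1.49, camera adjusted p = 3.3e-56), with log2 fold changes of -5.78 for GPX2, -4.89 for ALDH3A1, -3.69 for AKR1B10 and -3.64 for AKR1C2. AKR1C2 and AKR1B10 have near-identical relatives, so the share of reads belonging to each copy is uncertain. ATF4 targets, which serve amino acid supply under stress, fell in 30 of 32 cases and rose in 1 (median -1.67, camera adjusted p = 1.4e-27). The asparagine synthetase gene ASNS, the serine synthesis gene PSAT1, the glutamine transporter gene SLC1A5 and TRIB3 had log2 fold changes of -2.73, -2.41, -1.74 and -4.49. NF-κB and inflammatory cytokine genes fell in 16 of 23 cases and rose in 5 (median -1.06, camera adjusted p = 2.4e-08, and adjusted p = 0.091 with an estimated correlation), with log2 fold changes of -4.83 for PTGS2, -3.92 for CXCL5, -3.72 for CXCL2 and -2.94 for BIRC3.

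Replication-dependent histone genes fell in 34 of 38 cases and rose in 2 (median -0.93, camera adjusted p = 4.7e-06, and adjusted p = 0.54 with an estimated correlation). Examples were HIST1H3F (-1.59 on the log2 scale) and HIST1H1E (-0.94), and copies of these genes can share reads. Genes of the G1/S transition rose in 22 of 32 cases and fell in 5 (median 0.36, camera adjusted p = 0.019, and adjusted p = 0.76 with an estimated correlation), such as FEN1 (1.52) and PCNA (0.83). Mitotic genes rose in 25 of 34 cases and fell in 3 (median 0.26, camera adjusted p = 0.039, and adjusted p = 0.76 with an estimated correlation), with KIF20A at 1.10 and ECT2 at -0.99. The mitotic call was lost when control library S2 (camera adjusted p = 0.050) or S3 (0.059) was left out and with library totals (0.089). Over all alternatives the adjusted p ran from 4.6e-04 in fry, which does not compare a list with other genes, to 0.76 in camera with an estimated correlation. Ribosomal protein genes rose in 68 of 77 cases and fell in 0 (median 0.26, camera adjusted p = 4.8e-04, and adjusted p = 0.66 with an estimated correlation), with RPL28 at 0.98. Of the 77 genes, edgeR gave 69 higher when adjusted over the list alone, and 0 lower at an unadjusted p below 0.05.

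Cholesterol synthesis genes rose in 16 of 24 cases and fell in 4 (median 0.40, camera adjusted p = 0.0061, and adjusted p = 0.61 with an estimated correlation), with log2 fold changes of 2.42 for INSIG1 and 0.87 for SQLE. INSIG1 restrains this pathway, and SQLE encodes squalene epoxidase.

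Lists that did not pass held members changed in both directions. Counts higher and lower under TGF-β1 were 11 and 8 of 20 YAP/TAZ targets, 5 and 4 of 15 lung epithelial identity genes, and 4 and 11 of 24 acetate and acetyl-CoA genes (camera adjusted p = 0.58, 0.73 and 0.094). For fatty acid synthesis they were 7 and 10 of 23, for fatty acid oxidation 4 and 9 of 21, and for histone acetyltransferases and deacetylases 13 and 13 of 32 (camera adjusted p = 0.85, 0.12 and 0.85). Glycolysis gave 6 and 8 of 21, the TCA cycle 11 and 9 of 27, and osmotic stress genes 8 and 10 of 20 (camera adjusted p = 0.86, 0.83 and 0.17). The unfolded protein response gave 13 and 5 of 23, interferon response genes 5 and 16 of 26, and checkpoint and antigen presentation genes 13 and 6 of 22 (camera adjusted p = 0.19, 0.19 and 0.86). Hypoxia targets gave 12 and 10 of 25, and Notch and Wnt targets 9 and 9 of 19 (camera adjusted p = 0.86 and 0.19). Single genes in these lists moved far: the pyruvate dehydrogenase kinase gene PDK4 fell from 38.2 ± 0.492 to 0.681 ± 0.102 CPM, the ATP citrate lyase gene ACLY rose by 1.09 on the log2 scale, and the acetyl-CoA synthetase gene ACSS2 and the checkpoint ligand gene CD274 moved by -0.29 and 0.48. The cholesterol synthesis gene HMGCS1 moved by 0.25 (edgeR adjusted p = 3.5e-04).

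Across the 31 lists with at least 5 tested members, 17 passed under TGF-β1, 12 upward and 5 downward. The calls for SMAD targets, epithelial genes, mesenchymal genes, collagens, integrins, matrix proteases, ATF4 targets and NRF2 targets held with an estimated correlation, 8 in all. Their camera adjusted p were then far larger, from 0.0034 for NRF2 targets and matrix proteases to 0.035 for ATF4 targets. Counts adjusted over the list alone were the same as those over all genes for 29 of the 31 lists, the exceptions being ribosomal protein genes and checkpoint genes (13 higher and 7 lower).

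The second question was which genes acetate changed in cells that also received TGF-β1. CDH1 rose from 1.46 ± 0.394 CPM with TGF-β1 alone to 45.5 ± 2.56 CPM with acetate, against 58.7 ± 2.80 CPM in control. The ubiquitin ligase component gene FBXO2 (ENSG00000116661.9, chromosome 1, 11648367 to 11655785) rose from 2.51 ± 0.277 to 42.3 ± 3.05 CPM, and the succinate receptor gene SUCNR1 (ENSG00000198829.6, chromosome 3, 151873643 to 151884619) rose from 8.41 ± 1.06 to 111 ± 5.73 CPM. The matrix glycoprotein gene TNC and the lipoprotein gene APOE rose from 6.06 ± 0.261 to 66.2 ± 1.55 CPM and from 2.37 ± 0.240 to 26.4 ± 3.59 CPM. In contrast, THBS1, which encodes the matrix protein thrombospondin-1 and an activator of latent TGF-β (ENSG00000137801.10, chromosome 15, 39581079 to 39599466), fell from 1917 ± 40.3 to 280.4 ± 32.9 CPM.

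AGR2 rose from 1.59 ± 0.176 to 29.01 ± 3.244 CPM. The small GTPase gene RHOU (ENSG00000116574.5, chromosome 1, 228735077 to 228746669) fell from 273 ± 4.33 to 46.7 ± 3.06 CPM, the nicotinamide methyltransferase gene NNMT from 319.6 ± 18.2 to 55.3 ± 2.54 CPM and IGFL1 from 21.8 ± 0.822 to 2.57 ± 0.287 CPM. ANGPTL4, a secreted inhibitor of lipoprotein lipase, and the potassium channel subunit gene KCNE4 fell by log2 fold changes of -2.47 and -2.46. Of these 12 genes the largest edgeR adjusted p was 7.9e-12, for ANGPTL4.

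**Figure D1:**
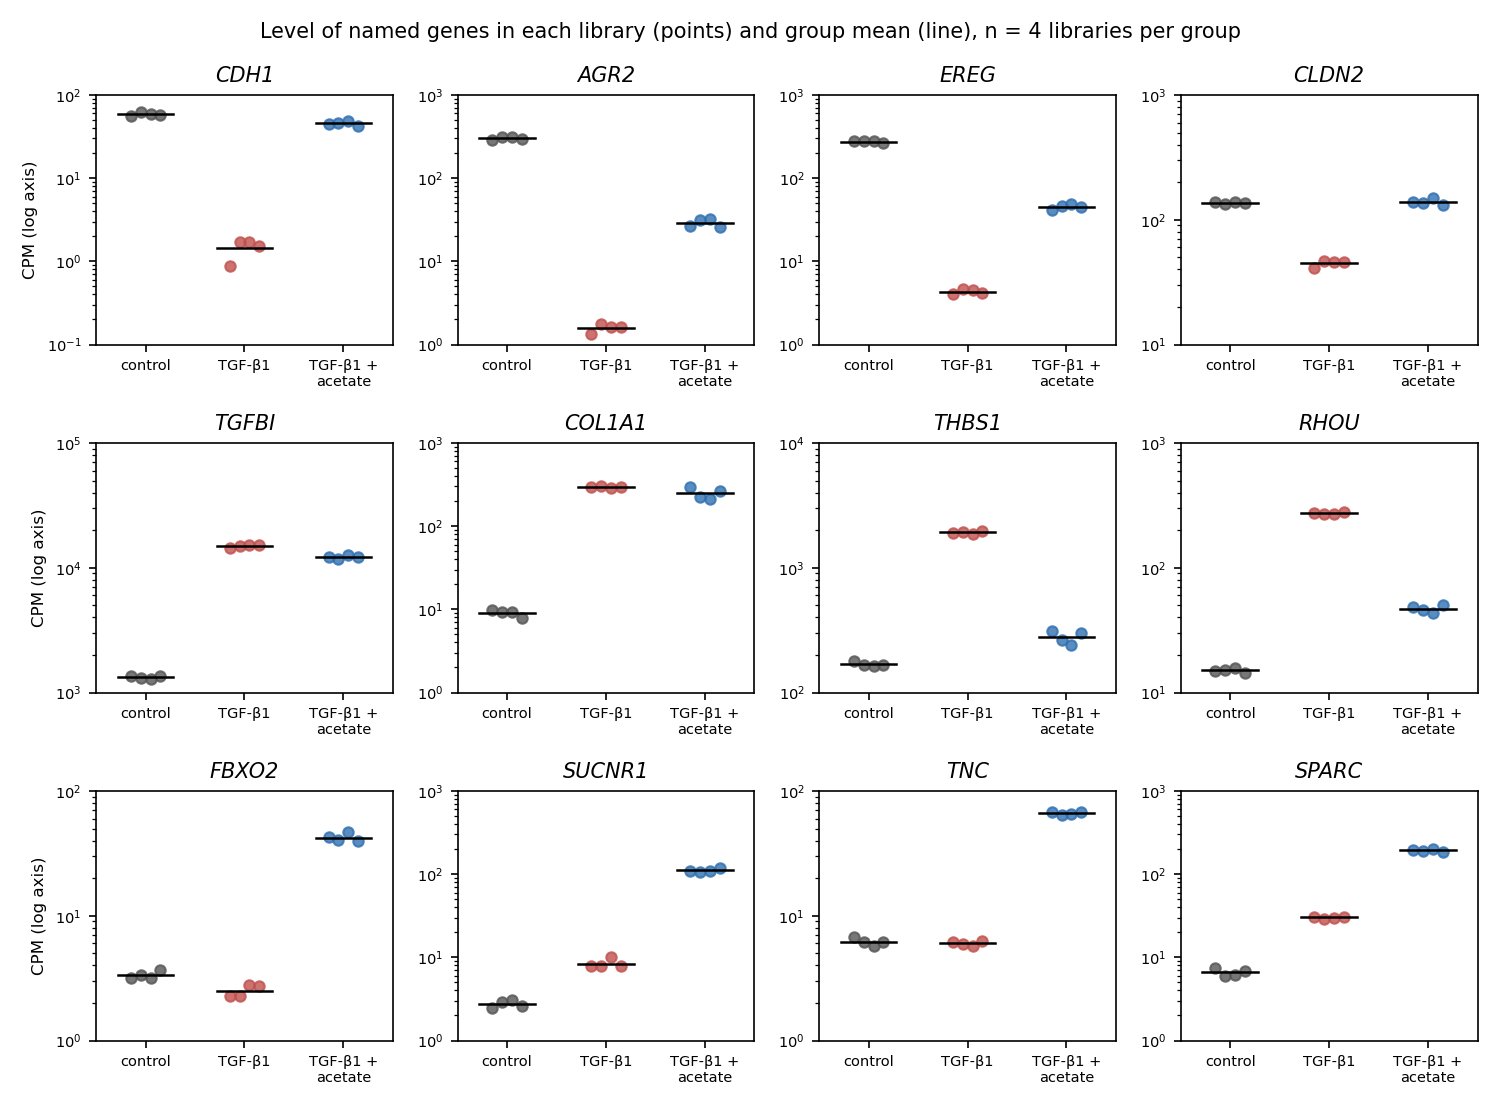
Level of 12 named genes in each library, in CPM on a log axis, with points for the libraries of the control, TGF-β1 and TGF-β1 plus acetate groups and a line at the group mean. With acetate CDH1 lay at 45.5 ± 2.56 CPM against 58.7 ± 2.80 in control, whereas TGFBI stayed at 12178 ± 372 CPM against 1328 ± 41.5 in control (mean ± SD, n = 4).

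The edgeR test passed 14229 of 22336 genes at an adjusted p below 0.05, 7437 higher and 6792 lower with acetate. At least 2-fold changes were uneven, with 2403 genes higher and 462 lower. Groups did not overlap for 57.4% of tested genes, against 2.86% by chance. No library had acetate without TGF-β1 or sodium without acetate, so effects of the sodium load, of osmolarity and of acetate itself stand together in this comparison. With library totals in place of composition scaling, the median over all genes shifted to 0.16 and the split became 9592 higher and 4699 lower, so the directions of small changes depend on the scaling.

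Epithelial junction and identity genes rose in 31 of 40 cases and fell in 3 (median 1.14, camera adjusted p = 2.3e-14, and adjusted p = 0.071 with an estimated correlation). CLDN2 rose from 44.9 ± 2.78 to 139 ± 8.31 CPM, and the protease inhibitor gene SPINT2 rose by a log2 fold change of 1.99. Integrin genes rose in 15 of 21 cases and fell in 5 (median 0.86, camera adjusted p = 7.8e-04, and adjusted p = 0.098 with an estimated correlation). ITGB4 (1.51) and ITGA6 (1.29), the laminin-binding integrin of epithelia, rose, whereas ITGB6 (-1.68) and ITGA1 (-1.21) fell.

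SMAD target and feedback genes fell in 16 of 25 cases and rose in 2 (median -0.27, camera adjusted p = 0.0014, and adjusted p = 0.19 with an estimated correlation). ANGPTL4, ID1, VEGFA, TGFB2 and SMAD7 had log2 fold changes of -2.47, -1.06, -0.49, -0.40 and -0.33. TGFBI fell by far less than ANGPTL4 (-0.29 on the log2 scale, and -0.16 with library totals).

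Mesenchymal genes divided: 13 of 32 rose and 13 fell, with a mean log2 fold change of 0.26 and a median of -0.00206 (camera adjusted p = 0.0013 upward, and adjusted p = 0.21 with an estimated correlation). With library totals that median was 0.13, and with single libraries left out it reached -0.06 (without TGF-β1 library S17). SPARC, a matricellular protein, rose from 30.1 ± 0.911 to 194 ± 5.84 CPM, and TNC, S100A4 and the BMP antagonist gene GREM1 rose by log2 fold changes of 3.46, 1.75 and 1.92. VIM, CDH2, ZEB1 and SNAI2 fell by smaller amounts, with log2 fold changes of -0.41, -0.21, -0.33 and -0.29, the last not passing with library totals (edgeR adjusted p = 0.066; 0.0013 to 0.066 over all alternatives). With library totals the log2 fold changes were -0.27 for VIM, -0.08 for CDH2 and -0.20 for ZEB1. FN1 did not pass (-0.06 on the log2 scale, edgeR adjusted p = 0.19).

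Collagen genes rose in 15 of 26 cases and fell in 6 (median 0.52, camera adjusted p = 0.001, and adjusted p = 0.19 with an estimated correlation). The type VI genes COL6A1 and COL6A2 rose by 1.79 and 2.08, COL4A5 rose by 0.94 and COL22A1 fell (-1.44). COL1A1 fell from 295 ± 8.23 to 250.3 ± 40.1 CPM (edgeR adjusted p = 0.02), a call lost in DESeq2 (adjusted p = 0.055), with library totals (edgeR adjusted p = 0.30) and without acetate library S23 (edgeR adjusted p = 0.068), the range over all alternatives being 4.0e-04 to 0.3. Matrix proteases and inhibitors rose in 16 of 25 cases and fell in 9 (median 0.56, camera adjusted p = 0.003, and adjusted p = 0.12 with an estimated correlation), with log2 fold changes of 2.04 for MMP10, 1.43 for PLAT, 1.17 for TIMP1 and 1.05 for TIMP4, while MMP2 fell (-0.25, and -0.12 with library totals).

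All 34 tested mitotic genes were lower with acetate (median -0.72, camera adjusted p = 1.0e-24, and adjusted p = 0.071 with an estimated correlation), with log2 fold changes of -1.17 for KIF20A, -0.97 for CCNA2 and -0.95 for TTK. Of 32 genes of the G1/S transition 29 fell and 2 rose (median -0.59, camera adjusted p = 2.3e-14, and adjusted p = 0.12 with an estimated correlation), with log2 fold changes of -1.18 for RRM2, -0.84 for MCM7 and -0.65 for RRM1. Replication-dependent histone genes fell in 34 of 35 cases (median -1.07, camera adjusted p = 2.2e-24, and adjusted p = 0.19 with an estimated correlation), for example HIST1H2BC (-1.39) and HIST1H1B (-1.19). Ribosomal protein genes fell in 75 of 77 cases (median -0.56, camera adjusted p = 3.7e-26, and adjusted p = 0.19 with an estimated correlation), with log2 fold changes of -0.92 for RPS12, -0.76 for RPS4X, -0.73 for RPS3A and -0.73 for RPL30.

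Cholesterol synthesis genes rose in 22 of 24 cases (median 0.51, camera adjusted p = 1.0e-10, and adjusted p = 0.12 with an estimated correlation), with log2 fold changes of 1.85 for TM7SF2, 1.29 for MSMO1, 0.85 for INSIG1 and 0.69 for HMGCS1. Fatty acid synthesis genes rose in 17 of 23 cases and fell in 2 (median 0.43, camera adjusted p = 0.0027, and adjusted p = 0.12 with an estimated correlation), with log2 fold changes of 1.32 for ELOVL7, 1.07 for ELOVL6, 1.02 for LPIN1 and -0.80 for GPAM. Fatty acid oxidation genes rose in 15 of 21 cases and fell in 2 (median 0.29, camera adjusted p = 0.003, and adjusted p = 0.27 with an estimated correlation). CPT1A, which controls fatty acid entry into mitochondria, rose from 20.2 ± 1.43 to 67.78 ± 0.7501 CPM, and PPARGC1A, PPARA and ACADVL rose by 1.68, 1.30 and 0.57 on the log2 scale.

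Genes of acetate and acetyl-CoA metabolism rose in 13 of 24 cases and fell in 5 (median 0.14, camera adjusted p = 0.026, and adjusted p = 0.22 with an estimated correlation). ACSS2, which makes acetyl-CoA from acetate in the cytosol, rose from 12.3 ± 1.31 to 31.3 ± 1.26 CPM, whereas ACLY, which makes it from citrate, fell (-0.53 on the log2 scale). PDK4, which holds back pyruvate use, rose by a log2 fold change of 4.12, and the monocarboxylate transporter gene SLC16A3 rose by 1.37. Osmotic stress genes rose in 16 of 20 cases and fell in 1 (median 0.65, camera adjusted p = 5.5e-07), the acetate call that held with an estimated correlation (adjusted p = 0.037). The aldose reductase gene AKR1B1 rose from 422 ± 7.80 to 2177 ± 175 CPM, and the water channel gene AQP1 and the taurine transporter gene SLC6A6 rose by 2.35 and 0.83. NKD1 rose by 2.47; it is an inhibitor of Wnt signalling and also belongs to the Wnt list.

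Notch and Wnt targets rose in 13 of 21 cases and fell in 3 (median 1.01, camera adjusted p = 4.6e-05, and adjusted p = 0.12 with an estimated correlation), with log2 fold changes of 2.60 for NOTCH3, 1.63 for AXIN2 and -1.02 for JAG1. Interferon response genes rose in 16 of 27 cases and fell in 2 (median 0.50, camera adjusted p = 0.0021, and adjusted p = 0.24 with an estimated correlation), with log2 fold changes of 2.93 for IFIT1, 1.85 for IFI6, 1.44 for OAS1 and 0.78 for SAMD9. Checkpoint ligand and antigen presentation genes rose in 14 of 21 cases and fell in 1 (median 0.40, camera adjusted p = 0.0053, and adjusted p = 0.23 with an estimated correlation). CD274, which encodes PD-L1, rose from 2.44 ± 0.284 to 4.88 ± 0.370 CPM, and HLA-B, HLA-F and HLA-E rose by 1.34, 1.36 and 0.59 on the log2 scale; HLA genes vary between cell lines and the reference, so their reads may be counted in part.

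NRF2 targets rose in 22 of 32 cases and fell in 6 (median 0.25, camera adjusted p = 7.1e-05, and adjusted p = 0.23 with an estimated correlation), with log2 fold changes of 1.86 for AKR1C1, 1.49 for ABCC2, 1.21 for EPHX1 and -1.05 for FTL. AKR1C1 has near-identical relatives, so the share of reads belonging to it is uncertain. ATF4 targets fell in 15 of 32 cases and rose in 9 (median -0.12, camera adjusted p = 0.044, and adjusted p = 0.68 with an estimated correlation), with log2 fold changes of -0.98 for MTHFD2, -0.89 for SLC7A5, -0.78 for SLC3A2 and -0.56 for XPOT. With single libraries left out the median ran from -0.23 (without acetate library S24) to -0.07 (without TGF-β1 library S17). The call was lost without TGF-β1 library S17 (camera adjusted p = 0.10) or acetate library S25 (0.057) and with library totals (0.058, median 0.01). Over all alternatives the adjusted p ran from 0.014 in fry to 0.68 in camera with an estimated correlation.

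Lists that did not pass under acetate had counts higher and lower of 13 and 17 among 31 actin cytoskeleton genes, 10 and 8 among 20 YAP/TAZ targets and 9 and 3 among 16 lung epithelial identity genes (camera adjusted p = 0.53, 0.82 and 0.091). Histone acetyltransferases and deacetylases gave 8 and 16 of 32, glycolysis 9 and 10 of 21, and the TCA cycle 6 and 9 of 27 (camera adjusted p = 0.13, 0.13 and 0.68). The unfolded protein response gave 7 and 7 of 23, NF-κB genes 6 and 10 of 21, and hypoxia targets 11 and 9 of 25 (camera adjusted p = 0.84, 0.5 and 0.82). Within them the glucose transporter gene SLC2A3 rose by 1.85 and the filamin gene FLNC by 3.41 on the log2 scale.

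Under acetate 21 of the 31 lists passed, 15 upward and 6 downward, and 1 held with an estimated correlation. Counts adjusted over the list alone were the same as over all genes for 24 lists. In the other 7 they were 18 and 2 for fatty acid synthesis, 15 and 3 for fatty acid oxidation, 10 and 10 for glycolysis, 2 and 30 for the G1/S transition, 17 and 1 for osmotic stress, 9 and 16 for ATF4 targets and 14 and 3 for Notch and Wnt targets, higher first.

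**Figure D2:**
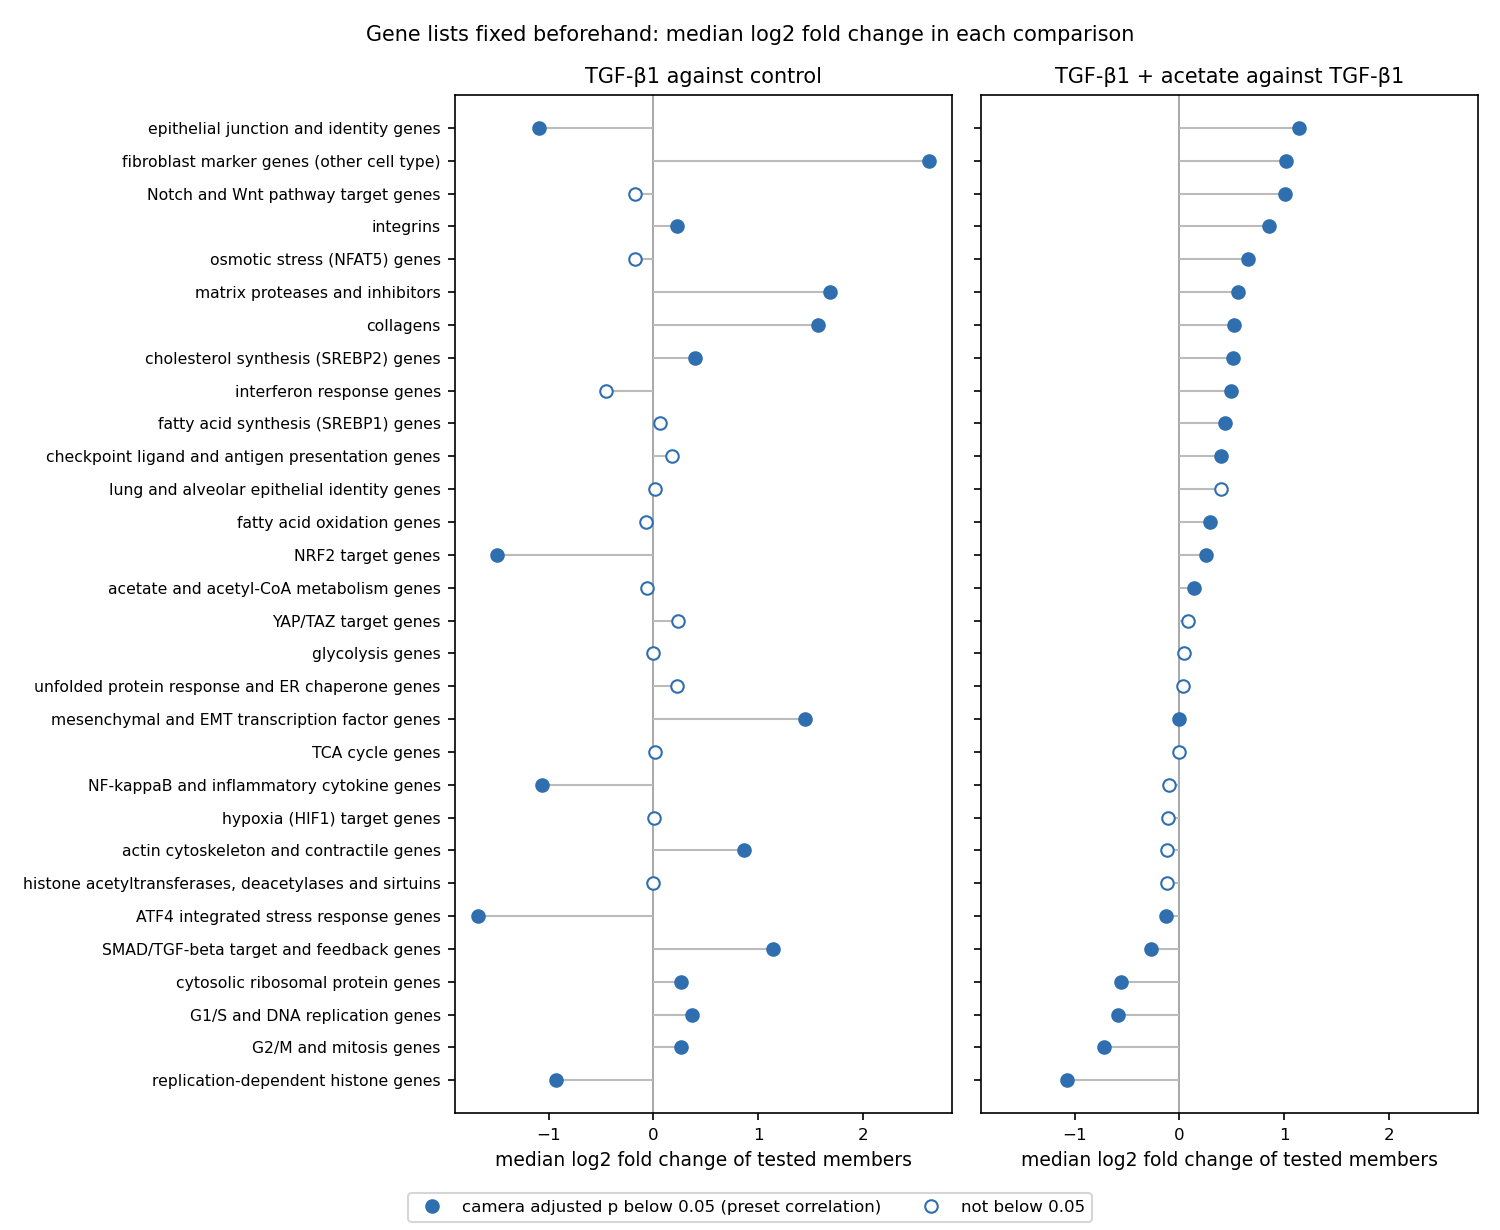
Median log2 fold change of the tested members of each of 30 gene lists, for TGF-β1 against control and for TGF-β1 plus acetate against TGF-β1. Filled points mark lists with a camera adjusted p below 0.05 at the preset correlation; the median for epithelial genes was -1.09 under TGF-β1 and 1.14 under acetate. With library totals the acetate medians shifted up with the median of all genes (0.16), and those of the mesenchymal, actin, histone acetyltransferase, TCA cycle, ATF4, NF-κB and hypoxia lists changed sign; under TGF-β1 those of the lung, fatty acid synthesis, TCA cycle and hypoxia lists did.

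Markers of other cell types were read in the same libraries. Fibroblast markers rose in all 9 tested cases under TGF-β1 (median 2.63, camera adjusted p = 0.0023, and adjusted p = 0.33 with an estimated correlation). Under acetate 6 rose and 3 fell (median 1.02, camera adjusted p = 0.0021, and adjusted p = 0.13 with an estimated correlation). THY1 was at 4.35 ± 0.313, 7.91 ± 0.760 and 44.4 ± 2.60 CPM and LUM at 0.407 ± 0.0550, 4.36 ± 0.352 and 15.3 ± 1.43 CPM in control, TGF-β1 and acetate libraries. Only 2 endothelial and 4 leukocyte markers were tested under TGF-β1, of which 2 and 3 rose and 0 and 1 fell. Under acetate 1 of 3 endothelial and 3 of 4 leukocyte markers rose and 0 and 1 fell, so neither list was tested as a set. CD14 was at 2.27 ± 0.209, 0.259 ± 0.0431 and 2.10 ± 0.182 CPM. No erythrocyte marker passed the count filter, and mitochondrially encoded genes were not analysed here.

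Cells with both agents were then compared with control. The epithelial genes lay on both sides of control, with 16 of 39 higher and 15 lower (median 0.03). CDH1 stayed lower than control by a small amount (log2 fold change -0.37, edgeR adjusted p = 3.8e-05), while CLDN2 did not pass (0.03, edgeR adjusted p = 0.57). AGR2 and AREG remained well below control (-3.37 and -3.47). Most genes of the TGF-β1 programme were above control: 18 of 25 SMAD targets, 29 of 32 mesenchymal genes and 19 of 25 collagen genes. Under TGF-β1 alone these counts were 19 of 25, 25 of 32 and 18 of 25, so not every gene above control had been raised before.

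TGFBI, COL1A1 and MMP2 were above control by log2 fold changes of 3.20, 4.79 and 4.50, and FN1, VIM, CDH2, SNAI2, SMAD7 and ZEB1 by 2.02, 0.94, 1.22, 2.00, 0.98 and 0.14. ATF4 and NRF2 targets were below control in 31 of 32 and 30 of 32 cases, with TRIB3 at -3.82, PSAT1 at -2.44 and ALDH3A1 at -4.32. Mitotic genes, higher than control in 25 cases under TGF-β1 alone, were lower than control in 30 of 34 cases, although KIF20A itself did not pass (-0.09, edgeR adjusted p = 0.24, and 0.0023 without control library S2; 0.0023 to 0.63 over all alternatives). Cholesterol synthesis genes were higher than control in 23 of 24 cases, with INSIG1 at 3.26 and HMGCS1 at 0.93. ACSS2, ACLY and CD274 lay above control by 1.05, 0.55 and 1.47.

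Genes far from control only in the presence of acetate included FBXO2 (3.66 against control, and -0.40 under TGF-β1 alone) and TNC (3.42, and -0.02 under TGF-β1 alone with an edgeR adjusted p of 0.79). In this fit of all 12 libraries edgeR passed 16051 of 22742 genes at an adjusted p below 0.05, 8221 higher and 7830 lower than control. At least 2-fold changes numbered 3263 upward and 1245 downward, and groups did not overlap for 64.0% of genes (2.86% by chance). In these lists the counts adjusted over the list alone were the same for 28 of the 31.

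The last question was whether acetate moved the genes that TGF-β1 had changed back towards control. Of the genes changed at least 2-fold by TGF-β1 and tested throughout, 1619 had been lowered, and acetate raised 1249 of them (77.1%), lowered 82 further and left 288 not passing. Of the 1962 raised by TGF-β1, acetate lowered 732 (37.3%), raised 619 further and left 611 not passing. Over all 22336 genes tested under acetate, 6792 were lower and 7437 higher, the base for these shares. By at least 2-fold, acetate moved 789 lowered genes back and 6 further, and 195 raised genes back and 226 further. The base for these 2-fold counts is uneven: of the same 22336 genes, 2403 were at least 2-fold higher and 462 at least 2-fold lower. Against control, 1149 of the lowered genes were still lower, 181 were higher and 289 did not pass. Of the raised genes 1852 were still higher, 5 were lower and 105 did not pass. Other genes of similar level were not compared. The median acetate change was 0.96 for the lowered genes and -0.08 for the raised genes. With the TGF-β1 libraries divided, 2 to each comparison, so that selection and test used different libraries, the mean shares were 66.9% of the lowered genes raised and 32.9% of the raised genes lowered, with median acetate changes of 0.93 and -0.06. The 5 largest opposite movements were those of AGR2, SPDEF, PLCXD3, AREG and CDH1. PLCXD3, a phospholipase C-like gene, was at 16.4 ± 1.41, 0.326 ± 0.110 and 11.1 ± 0.229 CPM in control, TGF-β1 and acetate libraries, and SPDEF, a transcription factor of secretory epithelia, at 15.1 ± 0.390, 0.0404 ± 0.0306 and 0.521 ± 0.109 CPM.

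The 5 largest movements in the same direction were rises from levels near the detection limit. CGB5, CST1, CRHR1, SLC2A5 and KLK6 were at 0.0584 ± 0.0262, 0.133 ± 0.0316, 0.0379 ± 0.0136, 0.0256 ± 0.0388 and 0.02641 ± 0.01002 CPM in control. With TGF-β1 they reached 7.28 ± 0.358, 0.985 ± 0.158, 1.205 ± 0.3084, 0.714 ± 0.208 and 0.858 ± 0.265 CPM, and with acetate 21.8 ± 2.33, 7.18 ± 0.219, 6.00 ± 0.861, 5.88 ± 0.313 and 3.09 ± 0.592 CPM. No fold against control is given for them or for SPDEF under TGF-β1, since 4 of the 5 control means and the SPDEF mean lay at or below the level of 3 counts per library.

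Over all genes passing in both comparisons, 6497 moved in opposite directions and 3776 in the same direction, 63.2% opposite. Independent calls would give 2370 genes up then down and 2236 down then up, against 3328 and 3169 observed. Both comparisons use the same 4 TGF-β1 libraries, so errors in single libraries among them would pull the changes apart. The libraries were therefore also divided between the comparisons. Dividing does not remove a shift common to all 4 TGF-β1 libraries, for example from shared handling. Such a shift would also give opposite signs and cannot be told apart from the treatment here. With 2 TGF-β1 libraries in each, the mean counts were 5501.5 opposite and 3184.8 in the same direction (63.3% opposite). Across 21512 genes, which are not independent replicates, the correlation of the log2 fold changes with the libraries divided was -0.34 (Pearson, SD 0.01 over the 6 ordered splits) and -0.23 (Spearman). In data simulated without effects the same quantity was -0.00195 when divided and -0.51 when not divided.

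**Figure D3:**
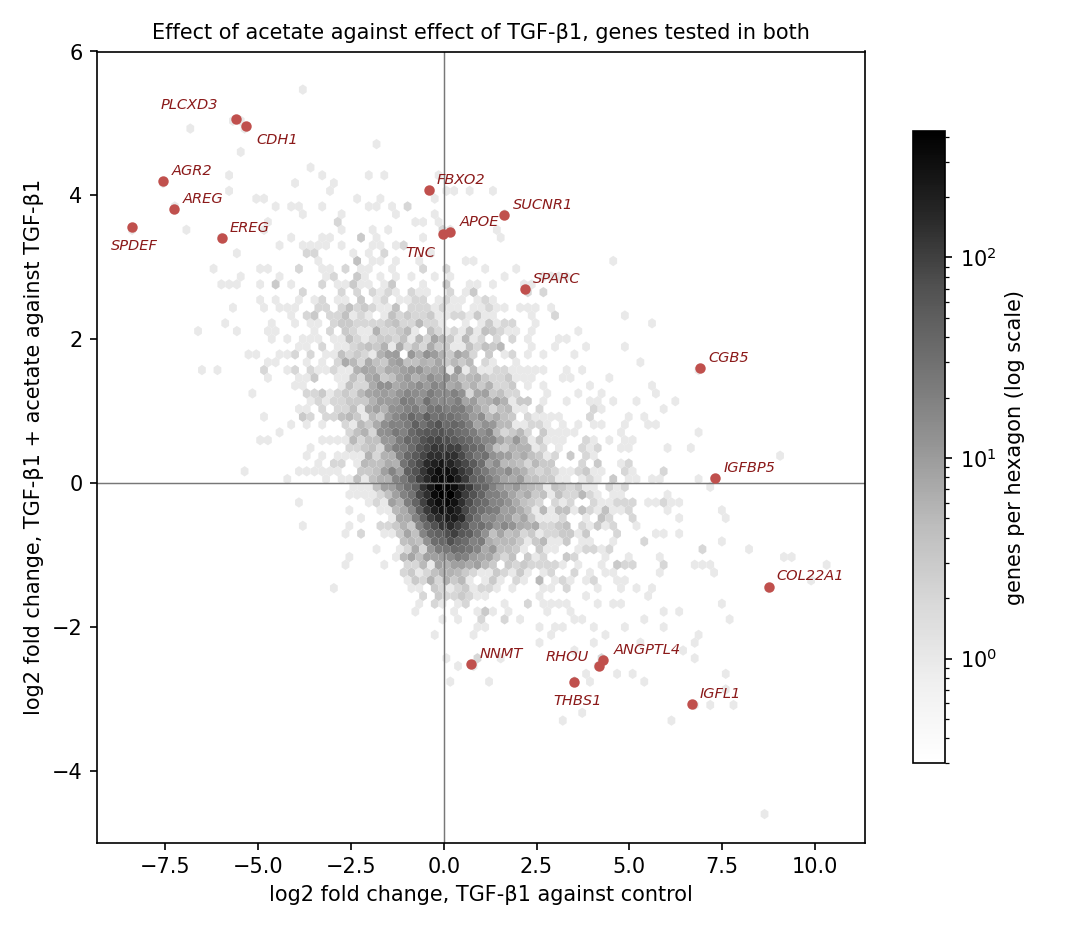
Log2 fold change of TGF-β1 plus acetate against TGF-β1 (vertical) plotted against that of TGF-β1 against control (horizontal), for 21512 genes tested in both; grey shading counts genes per hexagon on a log scale and red points mark named genes. AGR2, AREG, EREG and CDH1 lie far left and high, while IGFBP5 lies at 7.32 and 0.06 and COL22A1 at 8.75 and -1.44.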

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

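The 3 weighed patterns and their tests, with scaling by library totals and thinning among them, were chosen only after those results were seen, and for background reads the prediction too was written after the medians were known. The grouping of splits by the number of libraries exchanged and the separate values for sense-intronic and unconfirmed genes were also chosen afterwards. Within each group of 4 libraries, the highest or lowest library was compared with the rest by Dixon's test for 138 sets of values, of which 9 stood apart; chance alone gives about 6.90, or 5% of sets. Among library measures, control library S3 had 24294 genes with a count against 24358 to 24368 in the others. TGF-β1 library S15 had 9.44% of its counts in its 10 most abundant genes against 10.5 to 10.5%, and 0.0539% in sense-intronic genes against 0.0474 to 0.0479%. Among gene levels, S15 held CLDN2 at 40.7 CPM against 46.0 to 46.7, TGF-β1 library S18 held ACSS2 at 14.3 CPM against 11.5 to 11.8, and TGF-β1 library S17 held SUCNR1 at 10.003 CPM against 7.82 to 7.93. Acetate library S25 held SUCNR1 at 119.9 CPM against 108 to 109, and acetate library S24 held AKR1B1 at 2439 CPM against 2073 to 2105. Control library S1 held CD14 at 2.58 CPM against 2.12 to 2.20.

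The first weighed pattern is the excess of genes at least 2-fold higher with acetate, 2403 against 462 lower, a ratio of 5.20. The ratio was 4.75 with median-of-ratios size factors and 9.65 with library totals, so the choice among these scalings did not account for it. Library totals moved acetate values up, with a median over all genes of 0.16 against 0.026 in the reported fit. Size factors moved them down only slightly (median 0.0063), so these scalings cannot decide about a larger scaling error. The lower depth of the acetate libraries was argued against, with 5.25 after thinning all to the smallest total. Background from genomic DNA or unspliced RNA would raise antisense, sense-intronic and unconfirmed genes most. In the lower range of levels their median log2 fold change was 0.10 over 2828 genes against 0.43 over 4565 protein-coding genes, a difference of -0.33 (bootstrap SE 0.0178). Of the 2828 genes 2266 were antisense, whose counts may hold reads of the gene they overlap (see the last pattern). The pooled median is therefore a poor gauge of background. Unconfirmed genes alone had a median of 0.14 over 279 genes, -0.29 from protein-coding genes (bootstrap SE 0.0394). Sense-intronic genes took a larger share of counts with acetate (0.0565 ± 0.00261% against 0.0492 ± 0.00318% with TGF-β1, and 0.0567 ± 0.00235% in control, n = 4), but their own median was 0.13 over 283 genes, -0.30 from protein-coding genes (bootstrap SE 0.0349). The excess sat mainly in weakly expressed genes, with 1106 against 176 in the lowest of 4 equal groups of genes by level and 127 against 86 in the highest, and a broad rise of silent genes under acetate is a candidate explanation that was not tested.

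The lower level of ribosomal protein genes with acetate (median -0.56, 75 of 77 lower) is the next pattern. Scaling did not account for it, since 97.4% of these genes were called lower under each of the other scalings, size factors and library totals. To weigh a bias against transcripts of their length, GC content and level, each ribosomal protein gene was matched to 10 protein-coding genes, 360 distinct genes. The median over these matches was -0.34, below the limit of -0.28 set before that test was run. The bootstrap SE of the distance from that limit was 0.0208, with the limit recomputed in each draw. A bias shared with the matched genes could account for a large part. Length and GC content were those of the longest annotated transcript, with a median of 1857 bases for ribosomal protein genes. That transcript need not be the one expressed, so the match cannot decide about a bias by expressed length. Ribosomal protein genes lay below the matched genes by a further -0.22 (bootstrap SE 0.0283), so in these libraries part of the fall was not shared with them. The bootstrap SEs in this part draw genes or gene pairs as if independent and do not measure the spread between libraries. Ribosomal protein genes had an estimated inter-gene correlation of 0.57 under acetate, so for them such an SE is too small. Whether the matched genes fell for technical or biological reasons stays open, and the biological effect of acetate was not tested apart from it.

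The last pattern concerns antisense genes, whose changes followed those of the protein-coding gene they overlap. Under acetate the Spearman correlation over gene pairs was 0.81 for 2035 pairs with overlapping exons and 0.50 for 445 other pairs, a difference of 0.30 (bootstrap SE 0.0437). Under TGF-β1 it was 0.85 for 2006 pairs and 0.63 for 409, a difference of 0.21 (bootstrap SE 0.0394). Sense reads counted to the antisense gene could give this difference, and shared regulation of neighbours may account for the correlation that remains without exon overlap. Counts of antisense genes among the changed genes are therefore uncertain.

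Other divisions of the libraries were compared with the real groups. In each comparison 1 of the 35 splits of the 8 libraries, the real split, called any genes in edgeR, the tool run here. It gave 14742 genes for TGF-β1, 14229 for acetate and 16051 for acetate against control, and every other split gave 0. Every other split mixes treatments, and the treatment effects then widen the spread within its groups. The calls of 0 therefore do not exclude chance. At an unadjusted p below 0.05 the highest other splits gave 1336, 2575 and 3257 genes. For gene lists the real split gave the most in 1 of 35 cases each time, 17 lists under TGF-β1 against at most 16 in other splits and 21 under acetate against at most 17. Splits that exchanged 1 library per group, and so keep part of the real difference, passed 12 to 16 lists under TGF-β1 and 9 to 17 under acetate, and those that exchanged 2 passed 0 to 6 and 0 to 3. For the correlation of the effects, 36 of 100 splits of the 12 libraries gave a value as far below 0 as -0.34, the lowest other being -0.74. Groups of mixed treatment keep part of the real differences, so these splits are no reference without effects and decide nothing about chance; simulated data without effects, in which genes vary independently, gave -0.00195. For genes called in both comparisons with opposite sign, each split was refitted on the genes tested in both, which gives 6459 for the real groups in place of 6497. Of 100 splits 1, the real one, gave as many, and 98 of the splits gave none. The highest other split gave 6390. It had the acetate libraries in the place of TGF-β1, shared by both comparisons, between 2 mixed groups of control and TGF-β1 libraries. Differences of the acetate libraries from both mixed groups then count with opposite signs, so such a count can come from the arrangement alone.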

How the results depend on the processing

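The scaling by library totals and the thinning were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because the columns carry no replicate numbers, so the replicate blocks were not run. Counts of genes passing at an adjusted p below 0.05 stayed within 1.5 times of the reported ones except under a 2-fold limit (3883 genes for TGF-β1 and 2865 for acetate). Genes at least 2-fold lower with acetate numbered 298 with library totals against 462 in the reported fit. No gene called in both the reported fit and an alternative changed sign. Leaving out libraries gave 14297 to 14702, 13523 to 14302 and 15463 to 16184 genes. With an estimated correlation 8 and 1 lists passed. The correlation of effects was -0.36 with the TGF-β1 libraries not divided, -0.35 under the stricter filter and -0.34 to -0.33 with libraries left out. Library totals moved the median of all genes to -0.09 for TGF-β1 (6078 higher and 8676 lower, against 7518 and 7224) and to 0.16 for acetate (67.1% of called genes higher against 52.3%). They also reversed results that had not passed in the reported fit. For lists this means the direction given by camera, which need not have the sign of the median. The lists were glycolysis under TGF-β1 (median -0.10), and the TCA cycle (0.13) and the unfolded protein response (0.16) under acetate. The genes were FN1 (0.0762) and PSAT1 (0.11) under acetate. PSAT1 then passed (edgeR adjusted p = 0.028, with 0.028 to 0.93 over all alternatives). For the unfolded protein response fry and camera gave opposite directions (median 0.0319 in both). Signs also changed for PSAT1 under the stricter filter (0.00492), TNC under TGF-β1 without S17 (leaving out libraries, -0.0858 to 0.00492), and CLDN2 against control without S2 or S24 (-0.00951 to 0.0607). The direction given by camera for hypoxia targets under TGF-β1 changed without S17, while the median kept its sign (0.00719, against 0.0045 in the reported fit). With libraries left out that median ran from -0.0281 to 0.0271. The cause was not tested for these. Of the values for single genes, 5373 were the same, 5 weaker, 4 stronger and 6 reversed; for lists these were 690, 35, 14 and 5. Small changes can be missed, since edgeR recovered 43 of 48 and 33 of 50 simulated 1.5-fold changes.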

Other observations

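The grouping of genes by the root of their symbol was chosen after seeing the data, as were the genes named from it, and so were the tests of these families. The root is the symbol up to its first digit. It can also take in genes of other function, so the names below describe a root and not every member. Of 55 genes with the root EIF, which names translation initiation factors, 41 fell with acetate and 3 rose. Of 35 RNA helicase genes (DDX) 34 fell and 1 rose, and of 12 splicing factor genes (SRSF) 10 fell and 1 rose. Camera adjusted p for these 3 families were 1.6e-05, 3.8e-06 and 0.0014. With an estimated correlation their adjusted p were 0.3, 0.27 and 0.3. The 10 genes with the root MCM, which include those of the replicative helicase, the 10 RNA exosome genes (EXOSC) and the 8 chaperonin genes (CCT) all fell (camera adjusted p = 2.0e-06, 4.6e-04 and 0.0014, and adjusted p = 0.3, 0.27 and 0.43 with an estimated correlation). Log2 fold changes were -0.76 for EIF4A1, -0.55 for DDX39B, -0.66 for SRSF7, -0.64 for MCM4 and -0.60 for CCT5.

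Of 8 genes with the root BMP, which names bone morphogenetic proteins, 7 rose with acetate, among them BMP2 (1.45 on the log2 scale) and BMP6 (0.75). Of 8 lipid transporter genes (ABCA) 7 rose, among them ABCA7 (1.76) and ABCA1 (0.79). Semaphorin genes, which encode guidance cues, rose in 11 of 15 cases and fell in 4, with SEMA6B at 2.88 and SEMA3A at 1.59. Camera adjusted p were 4.9e-04, 5.3e-04 and 8.8e-04 for these 3 families, and adjusted p = 0.27, 0.27 and 0.31 with an estimated correlation. Under TGF-β1, sulfotransferase genes (CHST) rose in 10 of 11 cases, with CHST3 at 1.75 and CHST11 at 1.77, and metalloprotease genes (ADAMTS) rose in 7 of 11 cases and fell in 1, with ADAMTS6 at 3.54 and ADAMTS9 at 2.65. Their camera adjusted p were 2.2e-04 and 0.0013, and adjusted p = 0.49 and 0.43 with an estimated correlation. Of 234 families with at least 8 tested members 12 passed under TGF-β1, and of 238 under acetate 53 passed, 0 of them with an estimated correlation. The median log2 fold change of each family named here kept its sign under size factors and under library totals.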
